A study of Mus musculus with 9 samples.

How the data were processed

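RNA was taken from epididymal white adipose tissue of 9 mouse samples, 5 control and 4 UBKO, all given a beta3-adrenergic agonist. Per the labels' protocols, RNA was isolated on RNeasy columns, samples under a minimum RNA integrity number were not sequenced, and paired-end libraries were made with a TruSeq RNA kit. Whether that kit marked strand is not given in the sources used here, so overlapping and antisense genes could not be told apart. The submitters' processing notes name HISAT2, SAMtools 1.3.1, Cuffdiff and the genome build mm10. Their roles, the read counter and the annotation are not given in the sources used here.

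The authors deposited 1 table of 28481 genes with whole-number read counts and FPKM for each library. FPKM was checked against the counts: over 7151 genes with enough counts, the gene length implied by count and FPKM was the same in every library (coefficient of variation under 0.0001), so the authors scaled FPKM to the library's summed gene counts. The authors' deposited table also holds the log2 ratio of mean FPKM, a p-value and a q-value for UBKO against control, from a test that is not given in the sources used here. Of the gene IDs, 99.65% were found in GENCODE M21 for the same build, 99.1% of those with the same coordinates. Every row had a gene ID, and 0 columns of per-sample values were left unused. Groups and replicate numbers came from the sample titles.

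The deposited counts were tested with edgeR 4.0.16 in R 4.3.3 on all 9 libraries, which left 16123 genes. The fit used filterByExpr by group, TMM scaling, and glmQLFit and glmQLFTest with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. CPM values are scaled by TMM. The SE of a log2 difference was derived from the difference and its F statistic. Gene lists, 33 in all, were fixed before the data were examined. Lists with at least 3 tested genes were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, log2 CPM with a prior count of 2), repeated with an estimated correlation and with fry. An exact two-sided permutation test (scipy 1.17.1) compared each list's mean log2 level per library. The epididymis and testis list kept 2 tested genes, so its counts are given without a test. Members were named by the rule below for 21 lists: those that passed camera, and the beige, Ucp1-independent and canonical Wnt target lists. The other lists are given more briefly.

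Genes were named by a rule also fixed then: Ctnnb1; the 12 higher and 12 lower genes with the largest change past the threshold with a mean FPKM of at least 1 in either group, without predicted genes and antigen receptor segments; up to 4 members of each of the 21 lists with the smallest p; and Ucp1, Cidea, Dio2, Ppargc1a, Elovl3, Cox7a1, Cox8b, Adipoq, Lep, Fasn and Axin2. Tmem26, Gatm, Eci2, Acaca, Il7r, Gpx5, Lcn8, the genes of the glycolysis, interferon, immediate early, B cell, muscle and Schwann cell lists, and the epithelial and circadian clock genes were chosen after their values were seen. Some genes of the rule and of the lists are not reported here.

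Library totals of 15308480 to 17632709 counts set the precision, and the interval on a ratio of counts covers counting error only. No pair of replicates was a duplicate: the lowest chi-square per degree of freedom between replicates was 16.1. The fit was tested on simulated counts for 16123 genes in the same libraries. Of genes changed 2-fold 56% were recovered, of genes changed 4-fold 97%, with 9 false calls among 162, and camera called 0 of 30 unchanged lists. The changed genes were drawn only from those with a mean above 5 CPM. The recovery rates therefore do not cover lower genes, such as Ucp1 (1.71 CPM in control and 4.55 CPM in UBKO libraries). The simulated genes were drawn independently, while the correlation estimated within the lists reached 0.943, for mitochondrially encoded mRNAs. The simulation therefore does not show how often camera calls an unchanged list of correlated genes. The permutation test called 2 of 100 simulated unchanged list levels, and the enrichment test 1 of 100 unchanged terms drawn from 28481 genes. Each called all 100 simulated changes, which were large: list levels raised by 5 SD, and terms drawn in part from the called genes. These simulations do not show the power for smaller shifts. Their adjustment ran over the changed and unchanged simulations together, which let list levels at the smallest possible p pass. Over the 32 lists tested here, 1 list at that p alone could not pass, so these rates do not carry over to them.

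Alternatives fixed beforehand were DESeq2 size factors in place of TMM, no filter, each library left out in turn, the replicate number as a block, a DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) for genes with FPKM of at least 1 in at least 4 libraries, limma with array weights, z-scored list levels, and the authors' deposited comparison. Added after seeing the data were fits without Control replicates 1 and 2, without these and UBKO replicate 2, with scaling by total counts, without mitochondrial genes and pseudogenes, and list levels with each library left out.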

Results

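Gene expression was measured by RNA sequencing in epididymal white adipose tissue, the fat pad beside the mouse epididymis. Every animal had received an agonist of the beta3-adrenergic receptor, which drives lipolysis and heat production in fat. The series holds 5 control libraries and 4 libraries labelled UBKO. The series title names inactivation of Ctnnb1, which encodes beta-catenin, the transcriptional effector of canonical Wnt signalling, in adipocytes expressing the uncoupling protein Ucp1. Gene counts per library summed to between 15308480 and 17632709. The comparison is between genotypes under the agonist, and its question, from the title, is how loss of beta-catenin in these cells bears on browning, the gain of brown-fat features by white fat. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

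The targeted gene was examined first. Ctnnb1 (ENSMUSG00000006932, mm10 chromosome 9, 120929216 to 120960507) stood at 311 ± 36.7 CPM (gene counts scaled to library size; SD, n = 5) in control and 224 ± 56.7 CPM (SD, n = 4) in UBKO libraries. Its log2 difference was -0.47 (SE 0.17), which did not pass edgeR's quasi-likelihood test (adjusted p = 0.0976). Control replicates 1 to 5 had 339, 360, 294, 286 and 276 CPM. UBKO replicates 1, 2 and 4 had 180, 210 and 199 CPM, below every control, while the library labelled UBKO replicate 3 had 307 CPM, within the control range. Without that library the log2 difference was -0.66 (edgeR adjusted p = 0.0328). With all libraries it passed DESeq2's Wald test (adjusted p = 0.0481), and edgeR's test with scaling by total counts (log2 difference -0.88, adjusted p = 0.0123). It did not pass limma with array weights (log2 difference -0.45, adjusted p = 0.106), and passed edgeR's test in 1 of 9 fits that left out 1 library. Without Control replicates 1 and 2, which held epididymal transcripts, the log2 difference was -0.36 (edgeR adjusted p = 0.289), and without UBKO replicate 2 as well it was -0.30 (edgeR adjusted p = 0.386). The counts cover the whole gene and the whole tissue, genes overlapping Ctnnb1 held 1.17% as many counts, and the deleted part of Ctnnb1 is not given in the sources used here. The directions below include the library labelled UBKO replicate 3.

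In UBKO fat, 46 of 79 nuclear genes of oxidative phosphorylation and 7 of 22 of de novo lipogenesis were higher, and 17 of 20 macrophage, 18 of 24 extracellular matrix and 17 of 24 proliferation genes were lower. These lists passed camera with a preset correlation, while with an estimated one 0 of 32 lists passed (lowest adjusted p = 0.312 with an estimated correlation). Cox8b, a respiratory chain subunit of brown and beige fat, rose by 2.08 on the log2 scale (SE 0.37), from 45.7 ± 24.6 CPM (SD, n = 5) to 193 ± 20.1 CPM (SD, n = 4), with edgeR adjusted p = 0.00875. Csf1r, the receptor for the macrophage growth factor CSF1, fell by 2.44 (SE 0.20), from 187 ± 47.3 to 34.4 ± 3.65 CPM, with edgeR adjusted p = 0.00113, though genes overlapping it held 12.7% as many counts. Of 16123 genes tested, 626 were higher and 1219 lower in UBKO at an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaling by total counts in place of TMM moved the median log2 difference of all genes from -0.005 to -0.39 and gave 236 higher and 4482 lower genes. Control replicates 1 and 2 held epididymal transcripts, and without them 240 genes were higher and 782 lower. Without UBKO replicate 2 as well, with fewer libraries still, 411 were higher and 873 lower. The cause of these counts was not tested. With all libraries 1845 genes were called, while refits called 1208 without Control replicate 1 and 1136 without Control replicate 5. The refits called 946 without UBKO replicate 1, 756 without the library labelled UBKO replicate 3 and 765 without UBKO replicate 4. The higher genes numbered 353 without Control replicate 2 and 954 without Control replicate 3.

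**Figure D1:**
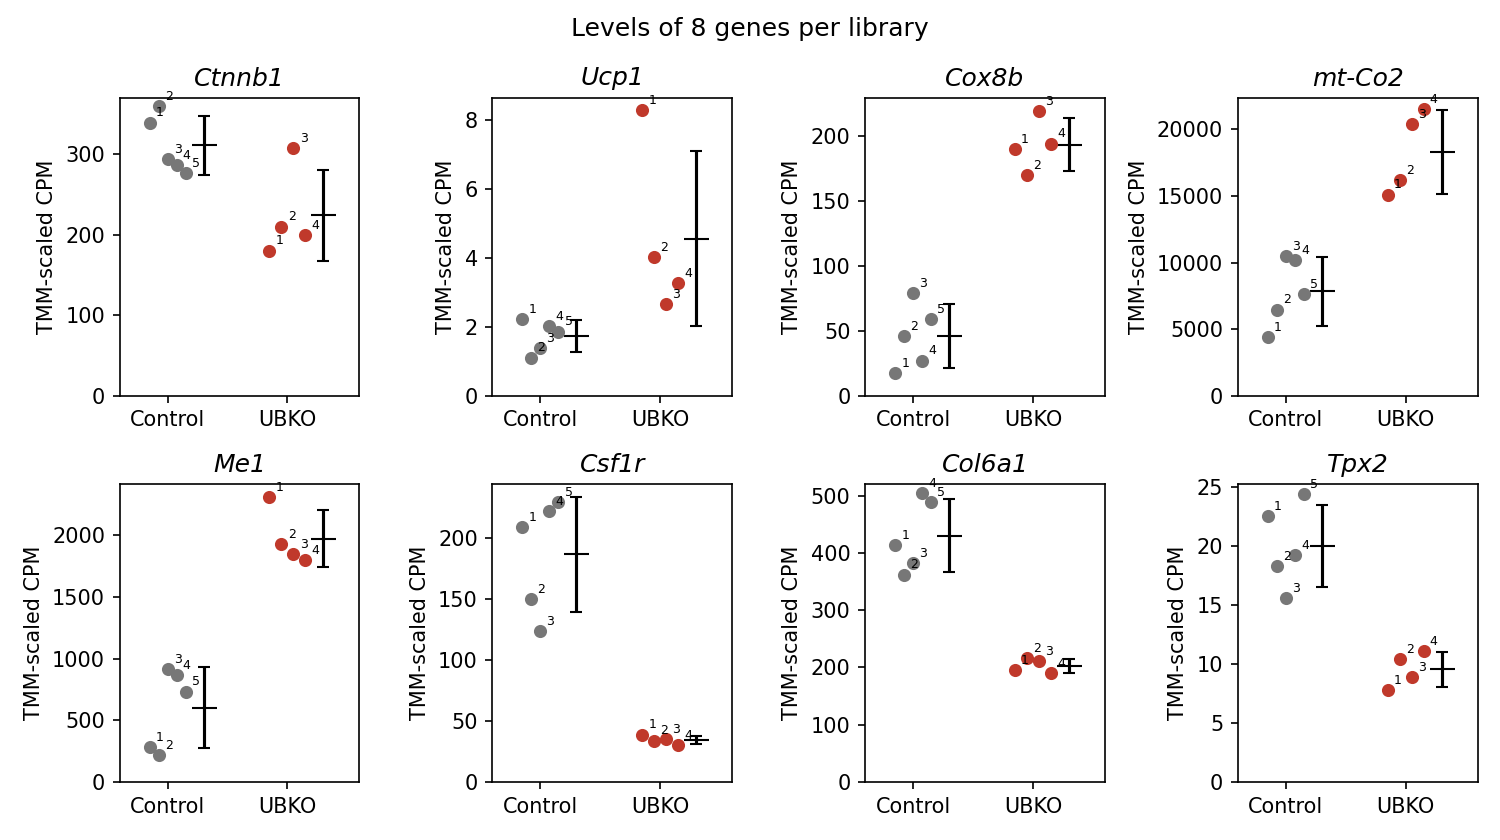
TMM-scaled CPM (linear axes from 0) of 8 genes in each library, control in grey (n = 5) and UBKO in red (n = 4), with replicate numbers beside the points and bars for the mean and SD. Cox8b and Me1 lie higher and Csf1r, Col6a1 and Tpx2 lower in all 4 UBKO libraries than in any control, while for Ctnnb1 the library labelled UBKO replicate 3, at 307 CPM, lies among the controls.

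The 12 higher genes with the largest change were Serpina3b, Slc25a48, H2-Q10, AA914427, Cox8b, Elovl6, Pcsk4, Mup3, Ciart, Acly, Me1 and Alb. Serpina3b, of a serine protease inhibitor family, rose by 2.37 on the log2 scale (SE 0.36, edgeR adjusted p = 0.00443), from 3.98 ± 1.57 CPM (SD, n = 5) to 20.5 ± 6.02 CPM (SD, n = 4). Slc25a48, of the mitochondrial carrier family, rose by 2.30 (SE 0.31, edgeR adjusted p = 0.00264), from 0.817 ± 0.304 to 4.05 ± 0.744 CPM. Elovl6, a fatty acid elongase, and Acly, which makes cytosolic acetyl-CoA from citrate, rose by 1.93 and 1.81 (edgeR adjusted p = 0.0386 and 0.0306). Serpina3b, H2-Q10 and Mup3 belong to multigene families whose members could share reads, and Ciart overlaps a gene with 15.1% as many counts, so their levels are uncertain. With scaling by total counts the call of Elovl6 ended (log2 difference 1.52, edgeR adjusted p = 0.0591). Without Control replicates 1 and 2 the calls of Mup3, Ciart, Acly and Alb ended (edgeR adjusted p = 0.103, 0.053, 0.115 and 0.152), while their log2 differences were 1.57, 1.65, 1.65 and 1.52, against 1.86, 1.85, 1.81 and 1.70 with all libraries. Of 9 fits that each left out 1 library, Elovl6, Mup3, Alb, Acly and Me1 kept their calls in 2, 1, 3, 4 and 6, with the highest adjusted p without UBKO replicate 1 for Elovl6, Acly and Me1 (0.103, 0.0877 and 0.0755) and without the library labelled UBKO replicate 3 for Mup3 and Alb (0.148 and 0.122, edgeR).

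Among the 12 lower genes with the largest change were Rhov, Shc4, Vsig8, Arg1, Itgad, Nptx1, Derl3, Galnt6, Adam8, Basp1 and Atp6v0d2. Arg1, the arginase of alternatively activated macrophages, fell by 4.80 on the log2 scale (SE 0.78, edgeR adjusted p = 0.00551), from 16.0 ± 13.3 CPM (SD, n = 5) to 0.562 ± 0.389 CPM (SD, n = 4). Itgad, an integrin subunit of leukocytes, fell by 4.56 (SE 0.60, edgeR adjusted p = 0.0024), from 9.32 ± 2.85 to 0.385 ± 0.301 CPM. Atp6v0d2, a subunit of the vacuolar proton pump, fell by 3.70 (SE 0.65, edgeR adjusted p = 0.0079), from 56.7 ± 31.2 to 4.35 ± 2.81 CPM. Rhov had 2 counts over the UBKO libraries and 143 over the controls, a ratio, per unscaled library total, of 0.0167 with a 95% exact interval of 0.00201 to 0.0616 that covers counting error only. Shc4 overlaps Eid1, which holds 832% as many counts, and Itgad overlaps genes with 10.6% as many, so both are uncertain. Without Control replicates 1 and 2 the calls of Nptx1 and Derl3 ended (log2 difference -2.05 and -2.42, against -4.10 and -3.85 with all libraries; edgeR adjusted p = 0.178 and 0.0502) and the log2 differences of Shc4 and Basp1 moved from -5.20 to -1.48 and from -3.74 to -2.54; limma with array weights did not call Shc4 (adjusted p = 0.0994). Of 9 fits that each left out 1 library, Shc4, Nptx1 and Derl3 kept their calls in 3, 3 and 7, with edgeR adjusted p of up to 0.124 for Shc4 without UBKO replicate 4 and, without the library labelled UBKO replicate 3, 0.126 for Nptx1 and 0.0729 for Derl3.

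Genes of thermogenic brown adipocytes shifted upwards, with 6 of 27 tested members higher and 0 lower (8 higher when adjusted over the list alone). Cox8b, Plin5, Otop1, Ucp1, Ppargc1a and Cox7a1 rose, though Otop1 was low, with 52 counts over the controls and 96 over the UBKO libraries. Ucp1, the proton channel that releases heat in brown and beige adipocytes, rose by 1.41 on the log2 scale (SE 0.36, edgeR adjusted p = 0.0365), from 1.71 ± 0.463 CPM (SD, n = 5) to 4.55 ± 2.54 CPM (SD, n = 4). Plin5, a lipid droplet protein that tethers droplets to mitochondria, went from 11.8 ± 1.01 to 23.7 ± 5.29 CPM (edgeR adjusted p = 0.00495). Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 0.91 and Cox7a1, a respiratory chain subunit, by 0.90 (edgeR adjusted p = 0.0349 and 0.0367). Cidea (log2 difference 1.49), Dio2 (0.27) and Elovl3 (0.33) did not pass (edgeR adjusted p = 0.0698, 0.688 and 0.652), though Cidea, which overlaps a gene with 10.6% as many counts, passed with DESeq2 (adjusted p = 0.00918). Scaling by total counts turned the sign of Dio2 and Elovl3. The list passed camera with a preset correlation (adjusted p = 0.00075) but not with an estimated one (adjusted p = 0.312 with an estimated correlation). Its median log2 difference was 0.43 (0.24 without Control replicates 1 and 2, 0.08 with scaling by total counts). In the same libraries general adipocyte markers had a median of 0.51 (0.17 without Control replicates 1 and 2, 0.15 with scaling by total counts) and macrophage markers of -2.41. The mean level differed by 0.44 for thermogenic genes and by 0.53 for adipocyte markers. Epididymis markers took 2.94% and 2.66% of the counts in Control replicates 1 and 2, and without these libraries the calls of Ucp1, Ppargc1a and Cox7a1 ended (edgeR adjusted p = 0.108, 0.0618 and 0.131), with log2 differences of 1.36, 0.96 and 0.67. The calls also ended with scaling by total counts (log2 difference 1.02, 0.54 and 0.52; edgeR adjusted p = 0.0714, 0.127 and 0.0897). These 3 genes kept their calls in 2, 2 and 3 of 9 fits that left out 1 library, with the highest edgeR adjusted p without UBKO replicate 1 for Ucp1 (0.0986) and without the library labelled UBKO replicate 3 for Ppargc1a (0.0936) and Cox7a1 (0.115).

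Of 15 beige adipocyte markers 1 rose and 4 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 0.878, adjusted p = 0.927 with an estimated correlation). Mtus1 rose by 0.68 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0174), a call that scaling by total counts ended (log2 difference 0.31, edgeR adjusted p = 0.054), and overlaps genes with 13.0% as many counts. Ear2, an eosinophil-associated ribonuclease, Epsti1, and Cd40, a receptor of antigen-presenting cells, fell by 1.91, 1.37 and 1.46 (edgeR adjusted p = 0.00772, 0.0054 and 0.0219). Tmem26 also fell by 1.39 (edgeR adjusted p = 0.03). Without Control replicates 1 and 2 the log2 difference of Cd40 was -1.50, and its call ended (edgeR adjusted p = 0.0578). The list's median (0.17) and its camera direction (lower) differ in sign, and scaling by total counts turned both. Among 15 genes of energy dissipation without Ucp1, Gpd2, the mitochondrial glycerol phosphate dehydrogenase, rose by 1.69 (SE 0.31, edgeR adjusted p = 0.00958), from 56.6 ± 22.5 CPM (SD, n = 5) to 182 ± 43.8 CPM (SD, n = 4). Gatm, an enzyme of creatine synthesis, fell by 0.85 (edgeR adjusted p = 0.0453). Of the other members that fell, Alpl, an alkaline phosphatase, and Ryr1, a calcium release channel, fell by 1.45 and 2.92, and Slc6a8, a creatine transporter, went from 28.7 ± 4.78 to 14.6 ± 5.32 CPM (edgeR adjusted p = 0.00718, 0.0127 and 0.0289, the last 0.111 without Control replicates 1 and 2, where the log2 difference was -0.86 against -0.97). Ryr1 was low, with 173 counts over the controls and 14 over the UBKO libraries. Adjusted over the list alone 3 rose and 4 fell, and the list did not pass camera (adjusted p = 0.765, adjusted p = 0.844 with an estimated correlation).

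Of 79 nuclear subunits of oxidative phosphorylation, 46 rose and 0 fell, with a median log2 difference of 0.64 (65 rose and 2 fell when adjusted over the list alone). That median was 0.27 with scaling by total counts and 0.47 without Control replicates 1 and 2. Ndufb5 and Ndufb11 of complex I rose by 0.89 and 0.78, Atp5j2 of the ATP synthase by 0.91 and Cox6c of cytochrome c oxidase by 1.15, with edgeR adjusted p between 0.00423 and 0.00678. Ndufb5, Ndufb11 and Cox6c overlap genes with 10.5%, 13.0% and 28.4% as many counts. The nuclear list passed camera (adjusted p = 1.3e-22, adjusted p = 0.312 with an estimated correlation). Of 13 mRNAs encoded by the mitochondrial genome, 11 rose, with a median of 1.12 (13 when adjusted over the list alone; camera adjusted p = 1.49e-09, adjusted p = 0.312 with an estimated correlation). Their median was 0.76 with scaling by total counts and 0.82 without Control replicates 1 and 2. Adipocyte markers had a median of 0.51 in the same libraries (0.15 with scaling by total counts, 0.17 without Control replicates 1 and 2) and macrophage markers of -2.41. mt-Nd1 rose by 1.19 (SE 0.27), from 11800 ± 3670 CPM (SD, n = 5) to 26800 ± 3860 CPM (SD, n = 4), with edgeR adjusted p = 0.0217, and mt-Co2 and mt-Nd2 by 1.23 and 1.22 (edgeR adjusted p = 0.0222 and 0.0254). Nuclear pseudogene copies could share reads with these transcripts, and mt-Nd1, mt-Co2 and mt-Nd2 kept their calls in 4, 5 and 5 of 9 fits that left out 1 library (highest edgeR adjusted p = 0.0806, for mt-Nd2 without UBKO replicate 4). The mitochondrial chromosome took between 8.78% and 17.8% of the counts in controls, lowest in Control replicates 1 and 2, and between 20.1% and 25.4% in UBKO libraries.

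Of 24 genes of the tricarboxylic acid cycle and pyruvate entry, 10 rose and 0 fell (20 rose when adjusted over the list alone). Pdhb, a subunit of pyruvate dehydrogenase, went from 310 ± 79.0 CPM (SD, n = 5) to 764 ± 34.7 CPM (SD, n = 4; edgeR adjusted p = 0.00345). Pdha1, of the same complex, Idh3g, of isocitrate dehydrogenase, and Sdha, of succinate dehydrogenase, rose by 1.17, 1.03 and 0.82 (edgeR adjusted p = 0.0063, 0.00911 and 0.0186). Camera gave adjusted p = 8.22e-11 (adjusted p = 0.361 with an estimated correlation). In fatty acid oxidation 4 of 28 genes rose and 1 fell (13 and 1 when adjusted over the list alone; camera adjusted p = 4.44e-05, adjusted p = 0.513 with an estimated correlation). Eci2 rose by 0.40 (edgeR adjusted p = 0.0472). Acadl, Acat1 and Hadh, enzymes of mitochondrial acyl and ketone body metabolism, rose by 0.86, 0.81 and 0.74 (edgeR adjusted p = 0.0373, 0.0366 and 0.0434). Those 3 calls ended without Control replicates 1 and 2 (log2 difference 0.64, 0.58 and 0.53; edgeR adjusted p = 0.0603, 0.0747 and 0.0646) and with scaling by total counts (log2 difference 0.49, 0.45 and 0.38; edgeR adjusted p = 0.0575, 0.0557 and 0.0642). Cpt1a, which controls fatty acid entry into mitochondria, fell by 0.99 (SE 0.21, edgeR adjusted p = 0.0174; 0.0642 without the library labelled UBKO replicate 3), and had a log2 difference of -0.70 without Control replicates 1 and 2. The medians of the tricarboxylic acid cycle and fatty acid oxidation lists, 0.68 and 0.47, were 0.46 and 0.26 without Control replicates 1 and 2 and 0.32 and 0.11 with scaling by total counts, where adipocyte markers had medians of 0.51, 0.17 and 0.15. Macrophage markers moved the other way in the same libraries, with a median log2 difference of -2.41.

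Of 22 genes of de novo lipogenesis, 7 rose and 0 fell (13 rose when adjusted over the list alone). Slc25a1, the mitochondrial citrate exporter, rose by 1.46 on the log2 scale (SE 0.26), from 690 ± 242 CPM (SD, n = 5) to 1900 ± 156 CPM (SD, n = 4), with edgeR adjusted p = 0.00795. Acaca, acetyl-CoA carboxylase, rose by 1.43 (edgeR adjusted p = 0.03). Me1, which supplies NADPH, rose by 1.71 (SE 0.41), Tkt, of the pentose phosphate pathway, by 1.33 and the lipogenic regulator Srebf1 by 0.84 (edgeR adjusted p = 0.0273, 0.0157 and 0.0235). The call of Srebf1 ended without Control replicates 1 and 2 (log2 difference 0.65, edgeR adjusted p = 0.0528). Fasn, fatty acid synthase, had a log2 difference of 1.34 that did not pass (edgeR adjusted p = 0.0889; DESeq2 adjusted p = 0.0121). The list passed camera (adjusted p = 3.19e-07, adjusted p = 0.312 with an estimated correlation). Its median log2 difference was 0.91 (0.70 without Control replicates 1 and 2, 0.57 with scaling by total counts). Adipocyte markers had a median of 0.51 with all libraries (0.17 without Control replicates 1 and 2, 0.15 with scaling by total counts). Macrophage markers had a median of -2.41 with all libraries. Of 18 genes of triglyceride synthesis and lipid uptake, Gpat3, an acyltransferase of glycerolipid synthesis, alone rose, by 0.82, also when adjusted over the list alone (edgeR adjusted p = 0.0225; 0.0701 without Control replicates 1 and 2, with a log2 difference of 0.63). Camera gave that list adjusted p = 0.0012 (adjusted p = 0.513 with an estimated correlation).

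Of 22 lipolysis and lipid droplet genes Plin5 rose and Hilpda fell (5 rose and 1 fell when adjusted over the list alone). Hilpda, an inhibitor of lipolysis, fell by 1.26 (SE 0.32, edgeR adjusted p = 0.0333; 0.0941 without Control replicates 1 and 2, with a log2 difference of -1.10). Gnas, encoding the stimulatory G protein subunit, had a log2 difference of 0.36 that did not pass (edgeR adjusted p = 0.0709; DESeq2 adjusted p = 0.00264) and turned sign with scaling by total counts. The list's camera call (adjusted p = 0.0159, adjusted p = 0.615 with an estimated correlation) ended without Control replicates 1 and 2 (adjusted p = 0.431), and its median of 0.29 became -0.07 with scaling by total counts.

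Of 18 adipocyte markers, Retn, Cfd and Pparg rose, also when adjusted over the list alone. Retn, the adipokine resistin, went from 908 ± 142 CPM (SD, n = 5) to 2560 ± 474 CPM (SD, n = 4; edgeR adjusted p = 0.00177). Cfd, the adipokine adipsin, and Pparg, a nuclear receptor of adipocyte differentiation, rose by 1.20 and 0.78 (edgeR adjusted p = 0.0371 and 0.0423), and both calls ended without Control replicates 1 and 2 (log2 difference 0.87 and 0.52; edgeR adjusted p = 0.0656 and 0.0747). Adipoq, encoding adiponectin, had a log2 difference of 0.41 and Lep, encoding leptin, of -0.75, and neither passed (edgeR adjusted p = 0.287 and 0.116), while Lep passed with DESeq2 (adjusted p = 0.0485) and with scaling by total counts (edgeR adjusted p = 0.00923). The call of Pparg ended with scaling by total counts (log2 difference 0.41, edgeR adjusted p = 0.0664). The list passed camera (adjusted p = 0.000252, adjusted p = 0.545 with an estimated correlation). Adipocyte progenitor markers went the other way, with 5 of 17 lower and 0 higher (6 lower when adjusted over the list alone). Cd55, a complement regulator, Pdgfra, a growth factor receptor, and the matrix genes Fbn1 and Lum fell by 1.51, 1.51, 1.42 and 0.62 (edgeR adjusted p = 0.00238, 0.0141, 0.0147 and 0.0206). Pdgfra had 113 and 105 CPM in Control replicates 1 and 2 and 43.2 to 53.9 CPM in the other controls, and without those 2 libraries its log2 difference was -0.94 (edgeR adjusted p = 0.00542). Camera for the progenitor list gave adjusted p = 0.00567 (adjusted p = 0.513 with an estimated correlation).

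Among 16 endothelial markers Kdr, a VEGF receptor, and Emcn, a surface glycoprotein, rose by 0.82 and 0.67 (edgeR adjusted p = 0.024 and 0.0199), also when adjusted over the list alone. The log2 difference of Kdr was 0.58 without Control replicates 1 and 2 (edgeR adjusted p = 0.0434). The call of Emcn ended without Control replicates 1 and 2 (log2 difference 0.50, edgeR adjusted p = 0.0617) and with scaling by total counts (log2 difference 0.30, edgeR adjusted p = 0.0858). Of 12 mural and smooth muscle markers 0 passed edgeR's test, by either adjustment, with 7 at an unadjusted p under 0.05, 4 called by DESeq2 and 2 by limma with array weights. Acta2, smooth muscle actin, stood at 120 ± 21.2 CPM (SD, n = 5) and 216 ± 93.2 CPM (SD, n = 4; edgeR adjusted p = 0.0574, DESeq2 adjusted p = 0.009). Both lists passed camera (adjusted p = 0.00542 and 0.0156; adjusted p = 0.603 and 0.513 with an estimated correlation) but not without Control replicates 1 and 2 (adjusted p = 0.171 and 0.16). The endothelial median of 0.30 became -0.07 with scaling by total counts.

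Macrophage markers had the largest median shift of the lists that passed camera. Of 20 markers 17 fell and 0 rose, with a median log2 difference of -2.41 (19 fell when adjusted over the list alone). C1qa fell by 2.58 (SE 0.23) and C1qc, also of the first complement component, fell by 2.39 (SE 0.25). Mrc1, the mannose receptor, fell by 2.18 (SE 0.22), from 117 ± 31.4 CPM (SD, n = 5) to 25.8 ± 4.77 CPM (SD, n = 4), and edgeR adjusted p lay between 0.00126 and 0.00133 for these 3 genes. In all 4 UBKO libraries they lay below every control, and their calls held in all 9 fits that left out 1 library. Camera gave adjusted p = 1.92e-17 (adjusted p = 0.312 with an estimated correlation). Among 17 inflammatory cytokines and chemokines 6 fell and 1 rose (8 and 1 when adjusted over the list alone). The chemokines Ccl3, Ccl4 and Ccl7 fell by 3.41, 3.03 and 2.43, and Nos2, an inducible nitric oxide synthase, rose by 1.24 (edgeR adjusted p = 0.00577, 0.0118, 0.0176 and 0.0139). Ccl3 and Ccl4 were low, with 174 and 158 counts over the controls and 10 and 12 over the UBKO libraries. The call of Ccl7 ended without Control replicates 1 and 2 (log2 difference -1.77, edgeR adjusted p = 0.051). Ccl4 did not pass without the 3 libraries with epithelial transcripts (log2 difference -2.44, edgeR adjusted p = 0.0631). The list's camera adjusted p was 0.0156 (adjusted p = 0.312 with an estimated correlation), and 0.51 with scaling by total counts.

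Extracellular matrix genes fell, 18 of 24 passing the test and 0 rising (20 fell when adjusted over the list alone). Col6a1, a collagen VI chain, fell by 1.08 (SE 0.13), from 430 ± 63.6 CPM (SD, n = 5) to 203 ± 12.3 CPM (SD, n = 4), with edgeR adjusted p = 0.00185. Postn, the matrix protein periostin, and the other collagen VI chains Col6a2 and Col6a3 fell by 1.15, 1.13 and 1.14 (edgeR adjusted p = 0.00177, 0.00187 and 0.00238). Of 24 proliferation genes 17 fell and 0 rose (23 fell when adjusted over the list alone). Tpx2, a spindle assembly factor, fell by 1.07 (SE 0.17, edgeR adjusted p = 0.00443), and Ccnb2, a mitotic cyclin, Kif20a, a mitotic kinesin, and Cdc20, an activator of the anaphase-promoting complex, fell by 1.11, 0.94 and 0.92 (edgeR adjusted p = 0.00746, 0.0074 and 0.00822). Kif20a and Cdc20 overlap genes with 317% and 321% as many counts, so both are uncertain. Both lists passed camera (adjusted p = 1.5e-12 for each; adjusted p = 0.312 with an estimated correlation). In the same libraries macrophage markers had a median log2 difference of -2.41 and progenitor markers of -0.37, with 5 of 17 progenitor markers lower, and Fbn1 is in both the matrix and the progenitor list.

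Of 17 genes of the unfolded protein response 6 fell and 0 rose (9 fell when adjusted over the list alone). Sdf2l1, of the endoplasmic reticulum, fell by 3.14 (SE 0.60), from 29.3 ± 22.9 CPM (SD, n = 5) to 3.33 ± 0.506 CPM (SD, n = 4), with edgeR adjusted p = 0.0112. The chaperone Calr and Edem1, of protein degradation, fell by 1.34 and 0.83 (edgeR adjusted p = 0.03 and 0.00865). Sdf2l1 had 61.7 and 44.6 CPM in Control replicates 1 and 2 and 7.78 to 18.3 CPM in the other controls, and without those 2 libraries its log2 difference was -2.02 (edgeR adjusted p = 0.00891). Calr went to -0.78 without them and kept its call in 3 of 9 fits that left out 1 library (highest edgeR adjusted p = 0.0905, without the library labelled UBKO replicate 3). Camera gave this list adjusted p = 0.00468 (adjusted p = 0.312 with an estimated correlation). In the same libraries 17 of 20 macrophage markers were lower, with a median log2 difference of -2.41.

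**Figure D2:**
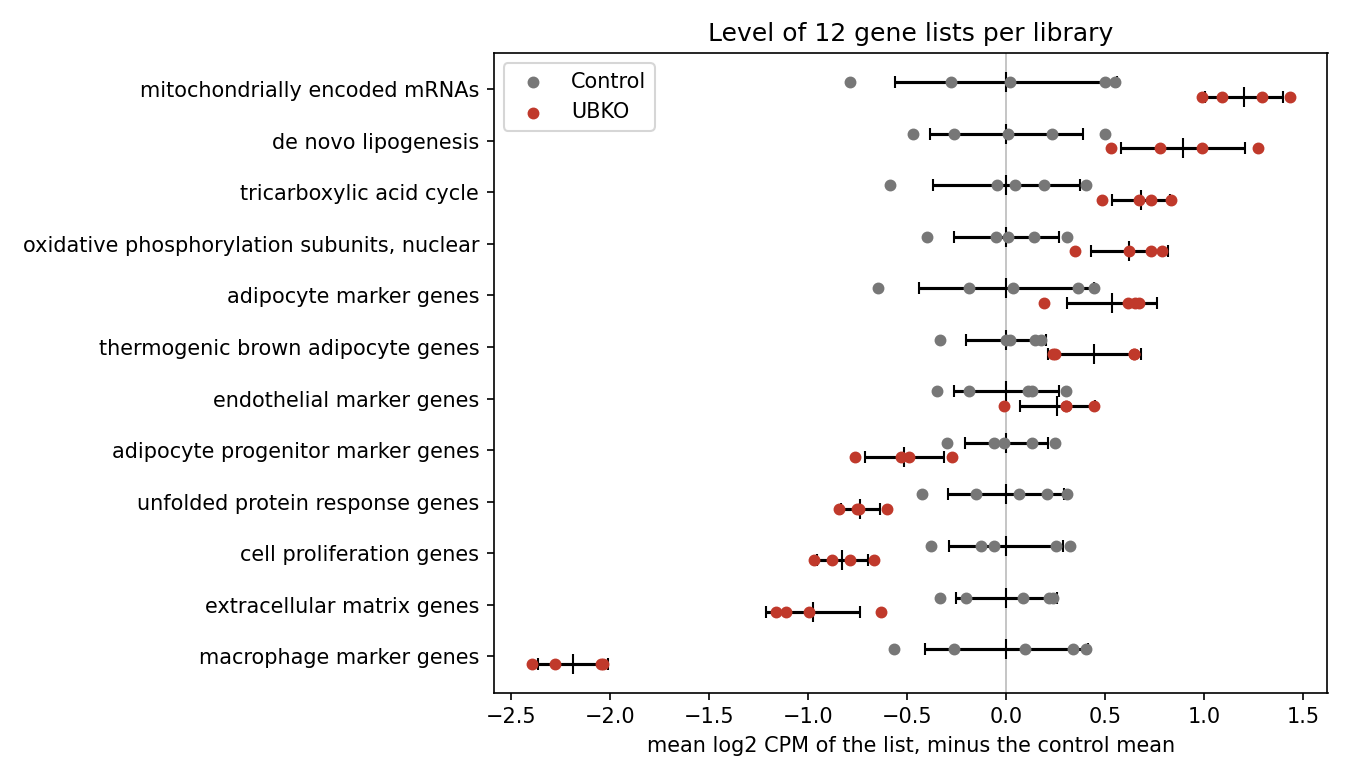
Mean log2 CPM over the genes of 12 lists in each library, minus the mean of the controls, for control (grey, n = 5) and UBKO (red, n = 4) libraries, with bars for the mean and SD. The macrophage list lies lowest in UBKO, with a level difference of -2.19, and the mitochondrially encoded list highest, with a difference of 1.20.

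Of 15 canonical Wnt targets 1 fell and 0 rose, by either adjustment, the all-gene one and that adjusted over the list alone (camera adjusted p = 0.503, adjusted p = 0.707 with an estimated correlation). Axin2, a feedback target of beta-catenin, stood at 12.7 ± 4.93 CPM (SD, n = 5) and 13.7 ± 6.18 CPM (SD, n = 4), with a log2 difference of 0.10 (SE 0.38, edgeR adjusted p = 0.897) whose sign turned with scaling by total counts. Cd44, a surface glycoprotein also carried by leukocytes, was the member that fell, by 1.88 (SE 0.31, edgeR adjusted p = 0.00602). The list's median was 0.09 while camera and the mean level pointed lower. Among 33 Wnt pathway components the secreted modulators Sfrp4, Sfrp5 and Sfrp2 fell by 1.79, 1.70 and 1.07 (edgeR adjusted p = 0.018, 0.0226 and 0.0339), also when adjusted over the list alone. Without Control replicates 1 and 2 the log2 difference of Sfrp2 was -1.05, and its call ended (edgeR adjusted p = 0.102). The targets Nkd1 and Myc, with edgeR adjusted p = 0.116 and 0.218, passed with scaling by total counts (0.038 and 0.0338). That scaling put the median log2 difference of all genes at -0.393. Without Control replicates 1 and 2 the log2 difference of Nkd1 moved from -0.956 to -0.361 (edgeR adjusted p = 0.484). That of Myc moved from -0.353 to -0.386 (edgeR adjusted p = 0.277). The component list passed camera (adjusted p = 0.043, adjusted p = 0.312 with an estimated correlation), but not without mitochondrial genes and pseudogenes (adjusted p = 0.0504). Its camera adjusted p was 0.0619 with the replicate block and 0.0031 without the 3 libraries with epithelial transcripts. Its mean log2 level in UBKO replicate 2, 4.22, lay within the control range of 4.16 to 4.34. In the other UBKO libraries it was 3.76 to 3.80.

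Across the 32 lists tested, 18 passed camera with the preset correlation and 0 with an estimated correlation. An exact two-sided permutation test of each list's mean level per library gave its smallest possible p, 0.0159, for 11 lists (adjusted p = 0.0463 over 32 lists). A list that reached this p alone could not have passed over 32 lists. The 11 calls therefore depend on each other, and some of these lists share genes. With z-scored unlogged levels 0 lists passed that test (lowest adjusted p = 0.0636), with 13 at an unadjusted p under 0.05. The 11 lists were the thermogenic, nuclear and mitochondrial respiratory chain, tricarboxylic acid cycle, lipogenesis, macrophage, extracellular matrix, proliferation, unfolded protein response, energy dissipation without Ucp1, and T and NK cell lists. The energy dissipation list was lower in UBKO, with a level difference of -0.196, and had permutation p = 0.587 with z-scored levels. The T and NK cell list had a level difference of -0.60 and did not pass camera (adjusted p = 0.1, adjusted p = 0.312 with an estimated correlation). In that list Il7r, a receptor of lymphocyte growth, fell by 2.90 (edgeR adjusted p = 0.00973), the only one of 9 tested members that passed (2 when adjusted over the list alone).

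In glycolysis and glucose uptake the enzymes Eno1 and Ldha rose by 1.10 and 0.72 and Hk1 fell by 0.86 among 19 genes, also when adjusted over the list alone. Camera gave that list adjusted p = 0.152 (adjusted p = 0.615 with an estimated correlation). Oas1a, an antiviral synthetase, fell by 1.51 among 20 interferon response genes (3 fell when adjusted over the list alone). The stress factor Atf3 and Jund fell by 2.69 and 0.83 among 19 immediate early genes (3 fell when adjusted over the list alone). Camera gave these lists adjusted p = 0.754 and 0.118 (adjusted p = 0.869 and 0.707 with an estimated correlation). Among cell type markers, Cd22 of B cells, Acta1 of skeletal muscle and the neurotrophin receptor gene Ngfr of Schwann cells fell by 1.82, 2.67 and 1.56, the only calls among 7, 4 and 10 genes. Adjusted over the list alone these lists held 2 higher and 2 lower, 1 higher and 1 lower, and 0 higher and 1 lower genes. Their camera adjusted p was 0.533, 0.765 and 0.846 (adjusted p = 0.734, 0.866 and 0.869 with an estimated correlation). Of 7 neutrophil and mast cell, 12 cadherin junction, 8 red blood cell and 14 mesothelial genes 0 passed edgeR's test, with 4, 1, 0 and 2 at an unadjusted p under 0.05, 2, 0, 0 and 0 called by DESeq2, and 2, 1, 0 and 0 by limma with array weights. Adjusted over the list alone 1 neutrophil and mast cell gene rose and 1 fell. Camera adjusted p was 0.39, 0.84 and 0.503 for the neutrophil and mast cell, cadherin and red blood cell lists (adjusted p = 0.615, 0.866 and 0.866 with an estimated correlation). Cadherin junction genes had a mean log2 level of 5.67 in UBKO replicate 2, which held epithelial transcripts, and of 4.70 to 4.84 in the other UBKO libraries.

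Epididymal transcripts were abundant in part of the controls. Gpx5, a secreted glutathione peroxidase of the epididymis, had 203959 and 195945 counts in Control replicates 1 and 2 and at most 6 in any other library. Lcn8, an epididymal lipocalin, had 65564 and 48719 counts there and at most 3 elsewhere. Genes of the epididymis and testis list took 2.94% and 2.66% of counts in these libraries and between 0.00306% and 0.0399% in the others. UBKO replicate 2 had 0 counts of Gpx5 but held the epithelial transcripts Krt8 (107 CPM), Epcam (41.1 CPM) and Mmp7 (181 CPM), against at most 3.08, 0.789 and 0 CPM in the other UBKO libraries. Most of its counts in the list came from Lcn2 (5863 counts). It also held Prm1 and Prm2 of that list, at 38 and 66 counts. Control replicate 1 had 17 and 34 counts of them and Control replicate 2 had 44 and 71. Elsewhere Prm1 had 0 counts and Prm2 at most 4. Tnp1 had 7 counts in UBKO replicate 2 and 8 in UBKO replicate 3. Without Control replicates 1 and 2 and UBKO replicate 2, 411 genes were higher and 873 lower in UBKO, and the macrophage median was -2.44. Mesothelial markers then passed camera (adjusted p = 0.00246), which they did not with all libraries (adjusted p = 0.175, adjusted p = 0.707 with an estimated correlation).

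**Figure D3:**
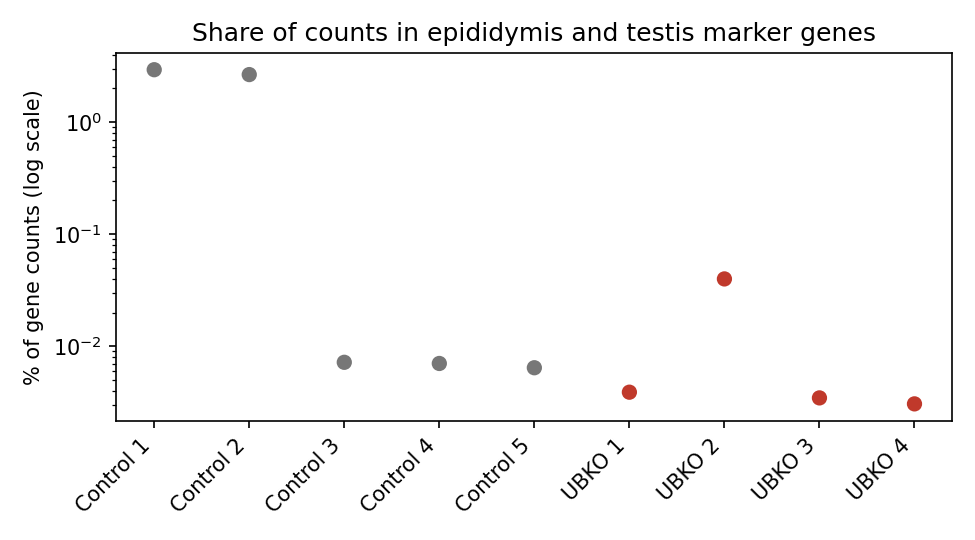
Share of gene counts (percent, log axis) falling in 23 epididymis and testis marker genes in each of the 9 libraries, control in grey and UBKO in red. Control replicates 1 and 2 stand at 2.94% and 2.66%, and the highest of the others, UBKO replicate 2, at 0.0399%.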

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

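All tests of explanations here were chosen after the values they rest on were seen. Among 294 groups of values examined for a library far from its group, about 1 in 20 would stand out by chance.

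Single libraries stood apart for 10 named genes and in 3 lists, in number no more than the chance rate above would give. Serpina3b had 1.23 CPM in Control replicate 1, against 4.31 to 5.01 in the other controls, and Atp5j2 had 103 CPM there, against 144 to 155. Cdc20 had 18.5 CPM in Control replicate 5, against 12.6 to 14.2. In UBKO replicate 1, Derl3 had 1.63 CPM (0.388 to 0.487 in the others), Elovl3 196 CPM (56.0 to 73.9) and Fasn 16700 CPM (9090 to 9960). In UBKO replicate 2, Rhov had 0.129 CPM (0 in the others), Lpin1 369 CPM (458 to 471) and Lum 77.9 CPM (66.9 to 68.6). Otop1 had 2.09 CPM in UBKO replicate 4, against 1.43 to 1.51. UBKO replicate 2 also stood apart in the mean log2 level of 3 lists: Wnt pathway components at 4.22 (3.76 to 3.80 in the other UBKO libraries), cadherin junction genes at 5.67 (4.70 to 4.84) and adipocyte markers at 9.81 (10.2 to 10.3). That library held epithelial transcripts, among them Cdh1 of the cadherin list at 25.6 CPM (at most 0.0717 in the other UBKO libraries), so chance need not be the source of its cadherin level.

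Genes of the epididymis and testis list, most of which the expression filter left out of the comparison, took 2.94% of counts in Control replicate 1 and 2.66% in Control replicate 2, against 0.00306% to 0.0399% in the other libraries. Reads of one of the 9 libraries counted in another are argued against, since a donor would exceed the recipient many times while Gpx5 differed 1.02-fold between both libraries. Epididymal tissue sampled with the fat may account for the signal: 15 of 23 measured genes of the list stood in both libraries at 10 times or more the highest of the others, just at the bound set for this explanation. The most abundant were Gpx5 (9610 and 9780 CPM), Lcn8 (3090 and 2430 CPM) and Adam7 (2140 CPM in each), and 2 genes of the list, Lcn2 and Sult1e1, had counts in every library. No biological explanation was tested.

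The number of genes called between genotypes, 1845, was reached by 2 of 100 splits drawn from the 126 possible, the real one included, so chance alone is unlikely to give it. The highest other split called 1996 genes and differed from the real one only in setting Control replicate 3 with the 4 UBKO libraries; the next highest called 3. Epithelial tissue in Control replicates 1 and 2 and UBKO replicate 2 is argued against as the source of most called genes' fold changes. Without these libraries the 1830 called genes still tested had a median ratio of new to old log2 difference of 0.947 (quartiles 0.848 and 1.04). These genes were called with those libraries included, which favours genes with little spread among controls, so the ratio does not cover other genes. Some results moved more. Shc4 went from -5.20 to -1.46 and the adipocyte marker median from 0.51 to 0.33, while the macrophage median went from -2.41 to -2.44. The count of calls did move with these libraries, to 1284 without all 3 of them. Why the split with Control replicate 3 called as many genes stays open. Ctnnb1 stood at the control level in the library labelled UBKO replicate 3, but other values there lay with its labelled group: the mean log2 macrophage level was 3.73 (3.61 to 3.97 in the other UBKO libraries) and Csf1r 34.9 CPM. In Control replicate 3 they were 5.44 (5.74 to 6.41 in the other controls) and 124 CPM, above every UBKO library. On the first principal component of log2 CPM (45.7% of the variance) the library labelled UBKO replicate 3 stood at 58.5. UBKO replicates 1 and 4 stood at 57.5 and 63.4, UBKO replicate 2 at -18.2 and the controls between -80.4 and 1.8. The lowest chi-square per degree of freedom between replicates, 16.1, was that of UBKO replicates 3 and 4. No test of the labels was run.

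Macrophage transcripts fell while mitochondrial transcripts rose. A loss of macrophages that raised every other cell type alike is argued against, because progenitor minus adipocyte marker levels moved from -3.02 ± 0.41 (SD, n = 5) to -4.07 ± 0.41 (SD, n = 4; exact permutation p = 0.0159, the smallest possible). A rise of mitochondrial transcripts only as far as adipocyte markers is argued against as well, since their difference rose by 0.67, from 2.79 ± 0.12 to 3.46 ± 0.24 (exact permutation p = 0.0159). Without the 3 libraries with epithelial transcripts the differences were -1.08 and 0.52, each with exact permutation p = 0.1, the smallest that 3 against 3 allow. Changes in both macrophage and progenitor shares, and an effect of genotype within adipocytes, stay open and were not tested.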

How the results depend on the processing

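The fits without Control replicates 1 and 2, without these and UBKO replicate 2, with scaling by total counts and without mitochondrial genes, and list levels with a library left out, were chosen after seeing the data. With all libraries and TMM 1845 genes passed, 626 higher and 1219 lower. The replicate numbers do not pair the samples: correlations of deviations were -0.179, 0.54, 0.095 and 0.164, and 2 of 4 UBKO libraries correlated best with their own number. With the replicate block 747 genes passed, 191 higher and 556 lower. A DESeq2 Wald test gave 3041 genes, 1285 higher; array weights gave 1053 higher; limma on log2(FPKM + 1) gave 4001, 273 higher and 3728 lower; no filter, which adjusts over more genes, gave 1110, 300 higher and 810 lower; the authors' deposited table gave 295 higher. Without Control replicates 1 and 2, 1022 passed (240 higher, 782 lower), of which 930 were shared with the full set in the same direction; without UBKO replicate 2 as well, 411 were higher. Scaling by total counts gave 4718, 236 higher and 4482 lower, with the median of all genes at -0.393 (-0.26 with limma on FPKM). Leaving out 1 library gave 756 to 2449 genes, 152 to 954 higher and 604 to 1495 lower: 756 without the library labelled UBKO replicate 3, 765 without UBKO replicate 4, 946 without UBKO replicate 1, 1136 without Control replicate 5 and 1208 without Control replicate 1, with 353 higher without Control replicate 2 and 954 without Control replicate 3. For Ctnnb1 the log2 difference ran from -0.66 to -0.38 over these fits, passing in 1 of 9, and was -0.362 without Control replicates 1 and 2 and -0.304 without UBKO replicate 2 as well, passing in neither. It passed with DESeq2 (-0.46), limma on FPKM (-0.82) and total counts (-0.88). Camera calls were 17 to 20 of 32 with a library left out, 13 by fry and 0 with an estimated correlation, against 18. List levels passed for 11 lists, for 0 with z-scored values, and for 0 with any library left out, where fewer splits give a larger smallest p. They were not run without Control replicates 1 and 2. Signs turned, none past the threshold: the Gnas log2 fold change was -0.015 with total counts; the Esam log2 fold change -0.019 with limma on FPKM and -0.046 with total counts; the Dio2 log2 fold change -0.051 and -0.122; the Elovl3 log2 fold change -0.122 and -0.015, and -0.259 to 0.521 with a library left out; the Axin2 log2 fold change -0.167 and -0.313, -0.065 with array weights, -0.022 with the block and -0.114 to 0.372 with a library left out; the Tnfrsf19 log2 fold change 0.602 without Control replicates 1 and 2 and 0.532 without UBKO replicate 2 as well. Camera directions turned for beige markers with the block (adjusted p = 0.722), with total counts (0.688) and with 3 of the libraries left out singly (0.627 to 0.974 over all 9), for energy dissipation without Control replicates 1 and 2 (0.92) and with total counts (0.725), and for canonical Wnt targets with total counts (0.906). Of 134 single results, DESeq2 size factors changed 0, the block ended 37 calls, and leaving out the library labelled UBKO replicate 3 ended 40. Except for the filter, the shifted median and the number of splits, the cause was not tested. The alternative pseudocount was for a table of FPKM alone and was not run. Ucp1 was low, at 1.71 CPM in controls, with 156 counts there and 273 in UBKO libraries, where it ran from 2.65 to 8.27 CPM. Whether depth limited such genes was not tested.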

Other observations

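The tests here were chosen after the data were seen. Among 323 KEGG terms carried by the table, each tested in both directions, genes higher in UBKO were enriched for oxidative phosphorylation (58 of 124 measured genes; Fisher's exact test, one-sided, adjusted p = 8.19e-43). They were also enriched for degradation of branched-chain amino acids (13 of 48; Fisher's exact adjusted p = 4.96e-06), propanoate metabolism (11 of 32; adjusted p = 3.14e-06) and the peroxisome (13 of 78; adjusted p = 0.00101). The genes lower in UBKO were enriched for the phagosome (44 of 137; Fisher's exact adjusted p = 1.13e-11), the lysosome (38 of 119; adjusted p = 5.92e-10) and osteoclast differentiation (32 of 107; adjusted p = 1.28e-07), but not for the cell cycle (12 of 118; adjusted p = 1) or protein processing in the endoplasmic reticulum (23 of 159; adjusted p = 0.259). The background was the 5799 tested genes with a term, of which 271 were higher and 568 lower, and genes within a term are not independent.

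The KEGG circadian rhythm term was not enriched among higher genes (4 of 29; Fisher's exact adjusted p = 0.306). Of 18 clock genes picked after the data were seen, most did not pass edgeR's test. Among those that did, Ciart, Per2, Cry1 and Nr1d2 rose by 1.85, 0.84, 0.63 and 0.60 on the log2 scale, and Arntl, the activator that Per and Cry proteins repress, fell by 1.33 (SE 0.38, edgeR adjusted p = 0.0496). Ciart, a clock repressor, moved from 3.01 ± 1.68 CPM (SD, n = 5) to 10.8 ± 1.81 CPM (SD, n = 4), with edgeR adjusted p = 0.0115, a call that ended without Control replicates 1 and 2 (log2 difference 1.65, edgeR adjusted p = 0.053). Dbp and Nr1d1 did not pass (edgeR adjusted p = 0.131 and 0.308). The times of tissue collection were not used here.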
